A study of Mus musculus with 16 samples.

How the data were processed

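RNA was measured by sequencing in 16 libraries from male mice of a mixed C57 and ICR background, wildtype or lacking miR-202. Isolated spermatogonia (2 wildtype, 2 knockout) and cultured spermatogonial stem cells (3 and 3) came from pups of 6 to 7 days, and isolated spermatocytes (3 and 3) from adults. Per the labels, RNA was extracted with TRIzol, libraries were made with a directional NEBNext Ultra kit, and they were sequenced on a HiSeq-X10. The FPKM values were computed by the authors and used as deposited, 1 value per gene symbol and library. The submitters' processing notes name TopHat2 2.0.6, Cufflinks 2.0.2 and the mouse build mm9 without giving their order or settings. Counts and read depth were not given in the sources used here, so the depth is unknown and no counting interval or floor was computed.

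Each file held 23021 rows with 22552 distinct symbols. The 259 symbols that occurred more than once (728 rows) were left out, which left 22293 genes. Of these, 25 symbols had the form of a date and were used but not named. Within each group the lowest Pearson correlation between libraries, across genes on the log2 scale, was 0.982 to 0.994.

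Values were analysed as log2(FPKM + 1), which understates fold changes of genes near or below an FPKM of 1. A single model with 1 mean per group was fitted to all 16 libraries with limma 3.58.1 (R 4.3.3, trend = TRUE, two-sided), over 14480 genes with 10 residual degrees of freedom. A gene was tested in a cell type when its FPKM was at least 1 in at least 2 libraries of that cell type. P-values were adjusted by Benjamini and Hochberg's method within each comparison, with a threshold of 0.05. Comparisons were knockout against wildtype in each cell type, the difference of these effects between cell types, and the wildtype cell types against each other. The groups, lists, the tests of these comparisons and most alternatives were chosen before the data were examined.

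Lists of marker and pathway genes were fixed in advance: published miR-202 targets, undifferentiated and differentiating spermatogonia, meiotic entry, cohesin, synaptonemal complex, double-strand breaks and recombination, pachytene spermatocytes, spermatids, piRNA pathway, germ cell RNA-binding proteins, G1/S, G2/M, microRNA machinery, Sertoli, Leydig, myoid, endothelial, macrophage, erythroid, fibroblast and feeder cells, immediate early and heat shock, interferon, apoptosis and p53, ribosomal proteins, histones, and X-linked and Y-linked genes. A list with at least 5 tested genes was tested against the other genes with camera, with a preset correlation of 0.01 and, as an alternative, an estimated correlation. The meiotic programme was the 200 genes with the largest rise, and the 200 with the largest fall, in wildtype spermatocytes over another wildtype group. That group was the cultures for the test in spermatogonia, and the spermatogonia for the test in cultures. No group mean thus served both the choice and the test, though both drew on the spread estimated from all 16 libraries. P-values of the meiotic programme were adjusted over its rising and falling genes in spermatogonia and cultures only. Those of the fixed lists were adjusted over all lists tested in a cell type.

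Named genes followed a rule: an adjusted p under 0.05, a mean FPKM of at least 5 in a group, no overlap between knockout and wildtype libraries, and the 12 largest changes in each direction. Unnamed gene models and microRNA or snoRNA genes were not named. Where none passed, the 5 smallest p in each direction were named as not passing. Mir202, the published targets and up to 4 members of each list with the smallest p were named as well.

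The files use mm9 and the annotation available here was GENCODE M21 on GRCm38, so no coordinates were used. Only 3' UTR sequences, the X and Y chromosomes and gene names were taken from it; 19545 genes had a 3' UTR. For each word of 7 bases found in the UTRs of at least 20 genes, the shift in log2 fold change of genes with a match was estimated by regression with UTR length and GC content (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), and the seed matches of miR-202-3p and miR-202-5p were ranked among these words. Figures were drawn with matplotlib 3.10.9.

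The procedure was tested on simulated data. Of 100 genes changed by 1 on the log2 scale, up or down, 77, 85 and 86 were recovered in spermatogonia, spermatocytes and cultures. Of 100 changed by 2, up or down, 94, 97 and 95 were recovered. False calls were 14, 13 and 11, which was 7.57%, 6.67% and 5.73% of the calls. A list of 20 genes raised by 0.5 was called in each cell type, and 0 of 20 unchanged lists were, at camera's adjusted p. The simulated noise was independent between genes, so it cannot show how often lists of genes that vary together are called wrongly. Seed words with no added shift had estimates of -0.006, 0.0006 and -0.031, the last of which ranked under 0.05.

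Alternatives were a pseudocount of 0.1, no filter on low values, median-ratio scaling, quantile normalization, no trend, a block for the replicate number, only the groups compared, an estimated correlation, each library left out in turn, and for the seed test no covariates, the shortest UTR and an 8-base match. A block with crossed numbers, a term for a set of spermatocyte libraries, a minimum FPKM met in both wildtype spermatogonia libraries and list differences over genes tested in both cell types were added after seeing the data.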

Results

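RNA was sequenced from male mouse germ cells of wildtype animals and of animals lacking miR-202, a microRNA. The 16 libraries formed 6 groups. Isolated spermatogonia came from pups of 6 to 7 days (2 wildtype and 2 knockout libraries), isolated spermatocytes from adults (3 and 3), and cultured spermatogonial stem cells from pups of 6 to 7 days (3 and 3). The stem cells were kept with GDNF and bFGF, growth factors on which such cultures depend. Each library listed 23021 rows of FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library. The FPKM of a library summed to 262109 to 395564, and 9494 to 12040 rows reached an FPKM of 1. Read depth was not given in the sources used here. The title of the series places the question at the start of meiosis and at recombination.

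Mir202, the targeted gene, was listed at 0 in all 16 libraries, wildtype and knockout alike. Of 579 symbols of microRNA precursors, 578 were at 0 in every library, so these values could not check the genotype labels. No other row of the files measured the deletion.

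The wildtype groups were compared first, to show which cells each preparation held. Ldhc, the lactate dehydrogenase of male germ cells, stood at 3557 ± 246 FPKM in spermatocytes (SD, n = 3) and at 3.73 ± 1.29 in isolated spermatogonia (n = 2). Kit, the receptor of differentiating spermatogonia, stood at 18.4 ± 1.63 FPKM in isolated spermatogonia and 2.65 ± 0.662 in cultured stem cells (n = 3). Gfra1, the GDNF receptor of stem cells, showed the opposite order, 20.3 ± 1.98 against 57.4 ± 16.1 FPKM. Isolated spermatogonia also carried Amh, a Sertoli cell hormone, at 185 ± 46.3 FPKM, Insl3, a Leydig cell hormone, at 101 ± 27.0, and Col1a1, a fibroblast collagen, at 113 ± 11.4. Cultured stem cells carried Col1a1 at 141 ± 62.2 FPKM and little Amh (0.30 ± 0.219), and spermatocytes carried little of either (0.306 ± 0.112 and 0.635 ± 0.157). With limma, 4671 genes were higher and 7619 lower in spermatocytes than in isolated spermatogonia among 13806 tested, and 3940 were higher and 2921 lower in cultured stem cells than in isolated spermatogonia among 12902. The count of genes higher in cultured stem cells fell to 2595 without wildtype spermatogonia replicate 1.

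Smooth muscle and matrix genes were among the 12 named for the largest falls in knockout spermatogonia; no list of matrix genes was tested. Acta2, smooth muscle actin, fell from 107 ± 28.1 to 13.7 ± 2.12 FPKM (SD, n = 2 and 2; log2 fold change -2.86, SE 0.47, adjusted p = 0.00189). Pdlim3, a protein of actin filaments, fell from 25.6 ± 7.76 to 3.48 ± 0.119 (-2.54), and Myh11, smooth muscle myosin, from 6.77 ± 1.06 to 0.858 ± 0.26 (-2.06). Lower too were Col4a4, a basement membrane collagen, from 9.48 ± 2.20 to 1.13 ± 0.377 FPKM (-2.29), Lama2, a laminin chain, from 18.7 ± 5.11 to 3.41 ± 0.191 (-2.14), and Mfap4, a microfibril protein, from 72.6 ± 11.0 to 15.3 ± 2.71 (-2.17). Mgp, Casq2, C1qtnf3, Bgn, Cdh11 and Fgl2 fell by 2.45, 2.35, 2.27, 2.13, 2.10 and 2.09 on the log2 scale. Mgp lost its call without wildtype replicate 1 or 2 or knockout replicate 1 or 2 (adjusted p = 0.0506, 0.154, 0.0696 and 0.132). A pseudocount of 0.1 ended the calls of Pdlim3, Mgp, C1qtnf3 and Bgn (adjusted p = 0.0751, 0.184, 0.0518 and 0.052).

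Genes higher in knockout spermatogonia were fewer and of mixed kinds. Hes1, a repressor in the Notch pathway, rose from 33.3 ± 3.16 to 72.7 ± 3.72 FPKM (1.11, SE 0.24, adjusted p = 0.0123). Tbx1, a T-box transcription factor, rose from 2.38 ± 1.07 to 7.90 ± 1.18 (1.43), Ybx2, a germ cell RNA-binding protein, from 3.30 ± 0.532 to 8.14 ± 2.02 (1.08), and Gadd45g, a growth arrest and stress gene, rose by 0.97 on the log2 scale. Mcpt4, a mast cell protease, stood at 0.422 and 0 FPKM in the wildtype libraries and 4.66 and 8.38 in the knockout libraries. Trnp1, Fabp9, Alg1, Crip2, Spns2, Hcn2 and Phlda2 rose by 1.31, 1.18, 1.10, 1.08, 1.03, 1.02 and 0.98 on the log2 scale. Mcpt4, Tbx1 and Hcn2 kept the call with any 1 library left out, but Hcn2 lost it with a pseudocount of 0.1 (adjusted p = 0.113). That setting also ended the calls of Hes1, Gadd45g, Trnp1, Fabp9, Alg1, Crip2, Spns2 and Phlda2 (0.24, 0.388, 0.178, 0.0978, 0.0538, 0.131, 0.222 and 0.202). Without wildtype replicate 1, Hes1, Ybx2, Gadd45g, Trnp1, Fabp9, Alg1, Crip2, Spns2 and Phlda2 had adjusted p of 0.0725, 0.0792, 0.0807, 0.221, 0.413, 0.112, 0.404, 0.138 and 0.50. Without wildtype replicate 2, Hes1, Gadd45g, Fabp9, Alg1, Crip2 and Spns2 had 0.105, 0.208, 0.092, 0.0772, 0.0879 and 0.0777. Without knockout replicate 1, Hes1, Gadd45g, Trnp1, Alg1, Crip2, Spns2 and Phlda2 had 0.0939, 0.082, 0.132, 0.105, 0.196, 0.111 and 0.284. Without knockout replicate 2, Hes1, Ybx2, Gadd45g, Fabp9, Alg1, Crip2, Spns2 and Phlda2 had 0.0661, 0.0673, 0.204, 0.38, 0.054, 0.15, 0.0609 and 0.054.

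Of 11997 genes tested with limma in isolated spermatogonia, 110 were higher and 691 lower in the knockout, 20 and 257 of them by at least 2-fold. All 801 calls separated the knockout from the wildtype libraries without overlap. That held for 56.1% of all genes tested, where chance gives 33.3%. Quantile normalization moved the split to 430 higher and 647 lower, so the higher share went from 13.7% to 39.9%. A lone library was assumed to vary like the other groups when one was left out. The counts were then 22 higher and 216 lower without wildtype replicate 1, 54 and 279 without wildtype replicate 2, 24 and 348 without knockout replicate 1, and 42 and 321 without knockout replicate 2. Of 39 calls of genes named here in spermatogonia, 14 held under all settings, 21 were lost with a pseudocount of 0.1 and 19 without some library.

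The list of differentiating spermatogonia genes shifted up in knockout spermatogonia, with a median log2 fold change of 0.49 over 12 genes (camera adjusted p = 0.00155, adjusted p = 0.353 with an estimated correlation). Of the 12, 11 lay above 0. Dnmt3b, a DNA methyltransferase, rose from 20.2 ± 0.967 to 32.5 ± 4.52 FPKM (0.65, adjusted p = 0.0325) and was the 1 member that rose, also when adjusted over the list alone. Kit stood at 18.4 ± 1.63 and 28.4 ± 2.25 FPKM (0.60, adjusted p = 0.179), and Sohlh1, a transcription factor of differentiation, at 65.3 ± 9.97 and 105 ± 19.2 (0.68, adjusted p = 0.128). Kit passed with quantile normalization (0.77, adjusted p = 0.0397) and with only the groups compared (adjusted p = 0.0172), and Sohlh1 with only the groups compared (adjusted p = 0.0206). Genes of undifferentiated spermatogonia had a median of 0.024 over 23 members (adjusted p = 0.166). Pou3f1, a transcription factor, rose from 8.45 ± 0.701 to 15.2 ± 1.73 FPKM (0.78) and was the 1 that rose there, also when adjusted over the list alone. Both calls were lost without wildtype replicate 1 or 2 or knockout replicate 1 or 2, with adjusted p of 0.279, 0.112, 0.249 and 0.059 for Dnmt3b and 0.207, 0.0663, 0.152 and 0.0536 for Pou3f1, and with a pseudocount of 0.1 (0.131 and 0.153). The median of the undifferentiated genes was -0.0050 without wildtype replicate 1 and -0.15 without knockout replicate 1.

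Lists of meiotic genes shifted up by small amounts in knockout spermatogonia. Pachytene spermatocyte genes had a median of 0.26 over 15 members (adjusted p = 0.00454, adjusted p = 0.236 with an estimated correlation). Of these, 2 rose, also when adjusted over the list alone: Ybx2, and Ovol1, a transcription factor of meiotic cells, from 0.982 ± 0.146 to 2.83 ± 0.133 FPKM (0.95). The piRNA pathway genes, which silence transposons, had a median of 0.20 over 22 members (adjusted p = 0.00426 and, with an estimated correlation, adjusted p = 0.55), with 1 that rose, also when adjusted over the list alone, 4921515J06Rik (0.60). Synaptonemal complex genes had a median of 0.21 over 15 members, and genes of double-strand breaks and recombination 0.13 over 30 (adjusted p = 0.00555 and 0.0137, and adjusted p = 0.55 for both with an estimated correlation); no member of either was called, also when adjusted over the list alone. Syce2, a central element protein, stood at 60.4 ± 7.65 and 87.3 ± 4.67 FPKM (0.53, adjusted p = 0.261) and passed with quantile normalization and with only the groups compared (adjusted p = 0.0475 and 0.0385). The pachytene and synaptonemal calls were lost without knockout replicate 2 (medians 0.19 and 0.34, adjusted p = 0.0523 and 0.0616), the recombination call without knockout replicate 1 or wildtype replicate 1 (adjusted p = 0.063 and 0.118), and the piRNA call without wildtype replicate 1 (adjusted p = 0.0904). The recombination median was 0.00059 and 0.079 in these fits, and the piRNA median 0.094. Ybx2 was lost without wildtype replicate 1 or knockout replicate 2 (0.0792 and 0.0673), and 4921515J06Rik without wildtype replicate 1 or 2 or knockout replicate 1 or 2 (0.216, 0.162, 0.238 and 0.0823) or with a pseudocount of 0.1 (0.0884).

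RNA of spermatids and spermatocytes was uneven among the spermatogonia libraries. Prm2 and Tnp2, which package sperm DNA, stood at 1.12 ± 0.797 and 0.906 ± 1.05 FPKM in wildtype and at 13.2 ± 16.7 and 11.8 ± 15.3 in knockout (adjusted p = 0.201 and 0.20), and the mean level of the spermatid list was 1.72 on the log2 scale in knockout replicate 2 and 0.628 to 0.696 in the other 3 libraries. Both genes passed without knockout replicate 1 (3.67 and 3.75, adjusted p = 0.0078 and 0.00592). Abundant spermatocyte transcripts, 39 genes with at least 200 FPKM in wildtype spermatocytes and less than 0.5 in wildtype spermatogonia, stood at a median of 0.067% and 0.134% of their spermatocyte level in the wildtype libraries and at 0.108% and 0.255% in the knockout libraries. Of the meiotic lists, the mean level of the pachytene list was highest in knockout replicate 2 (1.76 and 1.91 in wildtype, 2.03 and 2.14 in knockout replicates 1 and 2). The recombination and piRNA lists were highest in knockout replicate 1 (3.03 and 4.09), while knockout replicate 2 (2.83 and 3.82) lay within the wildtype range (2.76 and 2.86, and 3.67 and 3.85). The synaptonemal list was also highest in knockout replicate 1, with 3.61 and 3.73 in wildtype and 3.82 in knockout replicate 2.

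Stromal lists fell in knockout spermatogonia by the largest medians of the 26 lists tested. The fibroblast and feeder cell list fell by a median of 1.21 over 16 genes (camera adjusted p = 2.31e-10, adjusted p = 0.236 with an estimated correlation); 10 fell, or 13 when adjusted over the list alone, and all 16 lay below 0. Pdgfra, a receptor of mesenchymal cells, fell from 30.4 ± 9.89 to 8.67 ± 0.471 FPKM (-1.66), and Col6a1, a collagen, from 67.9 ± 15.9 to 19.5 ± 0.737 (-1.73). The peritubular myoid list, of the contractile cells around the tubule, fell by a median of 1.10 over 11 genes (adjusted p = 3.71e-07, adjusted p = 0.236 with an estimated correlation). Of these 7 fell, or 9 when adjusted over the list alone, with Tpm2, a tropomyosin, from 5.95 ± 1.92 to 1.56 ± 0.132 FPKM, a call lost with a pseudocount of 0.1 (adjusted p = 0.0915). No member of the Sertoli, Leydig or endothelial lists passed with the model of all libraries. Inha, a Sertoli cell hormone subunit, stood at 289 ± 62.8 and 170 ± 14.0 FPKM, and Cldn5, an endothelial junction protein, at 1.53 ± 0.259 and 4.20 ± 1.41; with only the groups compared they passed (adjusted p = 0.0176 and 0.00643).

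Further lists shifted in knockout spermatogonia. Cell cycle G1/S genes had a median of 0.16 over 27 members and histone cluster genes 0.14 over 40 (adjusted p = 0.0241 and 0.00454, with an estimated correlation adjusted p = 0.614 and 0.353). No G1/S gene was called, and 2 histone genes rose, Hist1h2bp (1.31) and Hist2h4 (0.99), or 1 when adjusted over the list alone; histone genes share reads with near-identical copies and are uncertain. X-linked genes had a median of -0.19 over 481 (adjusted p = 0.00426, adjusted p = 0.614 with an estimated correlation), with 1 that rose and 47 that fell, or 2 and 62 when adjusted over the list alone. Without knockout replicate 1 the G1/S median was -0.017, and without wildtype replicate 1 it was 0.029 and the histone median -0.0052, none past the threshold; the histone call was also lost without knockout replicate 2 (adjusted p = 0.389). The X-linked call was lost with a pseudocount of 0.1 and the G1/S call with quantile normalization (adjusted p = 0.0724 and 0.0519). Hist1h2bp and Hist2h4 lost their calls without wildtype replicate 1 (0.173 and 0.526) or 2 (0.13 and 0.0583).

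Single members moved in lists that did not shift. The heat shock genes Hspa1a and Hspa1b fell from 35.0 ± 2.40 to 11.7 ± 1.59 and from 45.0 ± 1.19 to 14.7 ± 2.14 FPKM (-1.51 and -1.55); the pair is nearly identical in sequence, so the division of reads between them is uncertain. Cdk1, the mitotic kinase, fell from 17.0 ± 0.0885 to 9.01 ± 1.82 (-0.86), and Kif23, a kinesin of cytokinesis, from 36.9 ± 3.17 to 22.3 ± 3.10 (-0.70). Mki67, a proliferation marker, did not pass (-0.77, adjusted p = 0.0769). It passed with only the groups compared and with the replicate block (adjusted p = 0.00379 and 0.0457). Bcl2, which blocks apoptosis, fell by 0.52 on the log2 scale and Ddx3y, a Y-linked helicase, by 0.63. Without wildtype replicate 1, Cdk1, Kif23, Bcl2 and Ddx3y had adjusted p of 0.153, 0.171, 0.344 and 0.431, and without knockout replicate 2 they had 0.177, 0.128, 0.116 and 0.132. Cdk1 was also lost without wildtype replicate 2 (0.0955), and Bcl2 and Ddx3y without knockout replicate 1 (0.0805 and 0.164). A pseudocount of 0.1 ended the calls of Hspa1b, Bcl2 and Ddx3y (0.113, 0.224 and 0.297), and the replicate block those of Bcl2 and Ddx3y (0.052 and 0.102). Bcl2 was also lost with quantile normalization and with only the groups compared (0.0841 and 0.107), and Ddx3y with median-ratio scaling (0.0503).

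The lists that did not shift in knockout spermatogonia had camera adjusted p from 0.0911 to 0.498. Their medians were 0.35 for endothelial cells, 0.21 for spermatids, 0.20 for Leydig cells, 0.14 for meiotic entry and retinoic acid, and 0.067 for microRNA machinery. They were -0.049 for ribosomal proteins, -0.051 for cohesin and separase, -0.056 for germ cell RNA-binding proteins, -0.15 for Y-linked genes, -0.16 for G2/M, -0.17 for apoptosis and p53, -0.23 for immediate early and heat shock genes, and -0.30 for Sertoli cells and for interferon genes. In the heat shock list 1 rose (Gadd45g) and 2 fell, or 1 and 3 when adjusted over the list alone; 1 fell in the p53 list, or 3 when adjusted over the list alone, and 0 in the interferon list, or 1 so adjusted. Camera compares a list with the other genes, and its direction was up for cohesin (mean -0.0099), RNA-binding (mean 0.025) and ribosomal genes (mean -0.060), against the sign of their medians. Without wildtype replicate 2 the Sertoli and heat shock lists passed (-0.55 and -0.29, adjusted p = 0.0168 and 0.0425). The spermatid, endothelial and G2/M lists passed without knockout replicate 1 (0.30, 0.55 and -0.24, adjusted p = 0.000252, 0.000386 and 0.0428). Without knockout replicate 2 the heat shock list passed (-0.23, adjusted p = 0.0135) and the spermatid median was -0.078. With no filter the spermatid, endothelial and heat shock lists passed (0.36, 0.36 and -0.23, adjusted p = 7.51e-05, 0.00173 and 0.0449), as did the heat shock list with quantile normalization (-0.20, adjusted p = 0.0314). Erythroid and macrophage genes were too few to test.

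In isolated spermatocytes, loss of miR-202 left few differences that passed the test. BC048609, a gene model without a known function, stood at 10.4 ± 1.28 FPKM in wildtype and 4.38 ± 1.01 in knockout (SD, n = 3 and 3; log2 fold change -1.09, SE 0.16, adjusted p = 0.0483) and was named after its values were seen. Cib4, a calcium-binding protein, stood at 5.31 ± 0.915 and 2.88 ± 0.337 (-0.69, adjusted p = 0.0586), Tex24, a testis gene, at 8.74 ± 2.76 and 4.27 ± 0.623 (-0.85), and Dusp13, a testis phosphatase, at 31.5 ± 1.62 and 20.2 ± 3.87 (-0.63). Adam34 and Gpx6 had log2 fold changes of -0.47 and -0.81. The genes above 0 with the smallest p, none of which passed, were Ssr4 (0.64), Loh12cr1 (0.73), Pisd-ps1 (1.98), Telo2 (0.54) and Vars2 (0.52), with adjusted p from 0.376 to 0.631. BC048609 lost its call without wildtype replicate 2 or 3 (adjusted p = 0.117 and 0.152) and with only the groups compared (0.999). It was also lost with the replicate block (0.353) and with a pseudocount of 0.1. Cib4 passed with no filter and with median-ratio scaling (0.0364 and 0.0334), and Adam34 with no filter and with quantile normalization (0.0401 and 0.0151). Cib4 also passed without wildtype replicate 1 or knockout replicate 1 or 2 (0.021, 0.0281 and 0.0393), Tex24 without wildtype replicate 2 (0.00728), and Gpx6 and Pisd-ps1 without knockout replicate 2 (0.00525 and 1.27e-10).

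Of 10271 genes tested with limma in spermatocytes, 0 were higher and 1 was lower; at an unadjusted p under 0.05 there were 105 and 313. The counts were 1 higher and 5 lower without wildtype replicate 1, 8 and 7 without knockout replicate 1, 2 and 36 without knockout replicate 2, 0 and 9 without knockout replicate 3, and 0 and 0 without wildtype replicate 3. Libraries also parted along another line: wildtype replicate 3 and knockout replicates 2 and 3 held 395 genes higher and 19 lower than the other 3 libraries. With that set of libraries as a term, 0 genes were higher and 12 lower in the knockout. This alternative was chosen after seeing the data, as the split of these libraries that called most genes. The p-values are not adjusted for that choice. Among the 12 were Tmem95, a sperm membrane protein (-0.97, adjusted p = 0.000582), and BC048609 (-1.21, adjusted p = 0.00404).

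Round and elongating spermatid genes were lower in knockout spermatocytes, with a median of -0.22 over 29 genes, 28 of them below 0 (camera adjusted p = 3.78e-06, adjusted p = 0.72 with an estimated correlation). The mean level of the list overlapped between the groups, at 6.02, 6.41 and 6.08 in wildtype and 5.52, 5.82 and 6.36 in knockout replicates 1, 2 and 3. None passed alone, and 3 fell when adjusted over the list alone. Catsper1 and Catsper3, sperm calcium channel subunits, stood at 10.4 ± 1.39 and 6.85 ± 1.81 and at 9.16 ± 0.638 and 6.07 ± 1.27 FPKM (-0.56 and -0.54), and Sun5, which anchors the sperm head, at 10.7 ± 1.09 and 6.20 ± 2.73 (-0.78). The Leydig cell list had a median of 0.62 over 7 genes, all above 0 (adjusted p = 3.78e-06, adjusted p = 0.537 with an estimated correlation), and 0 passed, also when adjusted over the list alone. Insl3 stood at 8.79, 12.4 and 45.0 FPKM in the wildtype libraries and 10.9, 81.8 and 98.0 in the knockout libraries, and Hsd3b6, a steroid enzyme, at 0.429 ± 0.38 and 1.71 ± 1.22; without knockout replicate 1 Hsd3b6 passed (1.29, adjusted p = 0.00431). With the set of libraries as a term the Leydig median was 0.28. Germ cell RNA-binding proteins had a median of 0.079 over 21 genes and microRNA machinery 0.13 over 10 (adjusted p = 0.0346 for each, and adjusted p = 0.643 and 0.537 with an estimated correlation), with 0 members called in either, also when adjusted over the list alone. That term ended both calls (adjusted p = 0.0536 for each). The RNA-binding call was also lost without wildtype replicate 1 or 3 or knockout replicate 2 or 3 (adjusted p = 0.115, 0.0596, 0.16 and 0.088), and the microRNA machinery call without wildtype replicate 1 or 3 or knockout replicate 1 or 2 (adjusted p = 0.115, 0.104, 0.0694 and 0.143). With no filter the RNA-binding call was lost (adjusted p = 0.169), and with median-ratio scaling or quantile normalization the microRNA machinery call (0.0566 and 0.0844).

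The lists that did not shift in knockout spermatocytes had camera adjusted p from 0.0947 to 0.735 and 0 members called. Their medians were 0.22 for fibroblasts, 0.20 for Sertoli cells, 0.17 for differentiating spermatogonia, 0.11 for meiotic entry, 0.090 for the synaptonemal complex, 0.087 for immediate early and heat shock genes, and 0.064 for apoptosis and p53. They were 0.045 for recombination, 0.044 for the piRNA pathway, 0.039 for undifferentiated spermatogonia, 0.029 for G1/S, 0.015 for cohesin and 0.00045 for ribosomal proteins, and below 0 for myoid cells (-0.054), G2/M (-0.055), X-linked genes (-0.057), histones (-0.070) and pachytene genes (-0.097). When adjusted over the list alone, 1 X-linked gene was higher and 2 were lower, and 0 passed in the others. The mean had the other sign than the median for undifferentiated (-0.088) and cohesin genes (-0.017), with a camera direction of down and up. Without knockout replicate 1 the X-linked median was 0.15 (adjusted p = 0.0002), and without wildtype replicate 3 or knockout replicate 2 or 3 it was -0.066, -0.17 and -0.18 (0.041, 1.49e-09 and 4.11e-06). The Sertoli list passed without wildtype replicate 2 or knockout replicate 1 or 2 (0.54, 0.53 and 0.50) and, in the other direction, without knockout replicate 3 (-0.61), as did the myoid list (-0.39). Without knockout replicate 1 the differentiating, heat shock and pachytene lists passed (0.42, 0.27 and -0.10). The X-linked list passed with a pseudocount of 0.1, with quantile normalization and with the set of libraries as a term (-0.15, -0.098 and -0.18, adjusted p = 0.00656, 2.44e-05 and 7.28e-06), and the differentiating list with no filter (0.18, adjusted p = 0.0204). Endothelial, erythroid, macrophage, interferon and Y-linked genes were too few to test.

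In knockout cultures of spermatogonial stem cells, chemokine, matrix and contractile genes were among the 12 named for the largest falls; no list of chemokine or matrix genes was tested. Ccl8, Ccl7, Ccl11 and Ccl2, which attract leukocytes, fell, Ccl8 from 41.2 ± 11.3 to 6.65 ± 2.24 FPKM (SD, n = 3 and 3; log2 fold change -2.47, SE 0.21, adjusted p = 2.6e-05) and Ccl2 from 158 ± 23.8 to 41.6 ± 9.06 (-1.91). Mmp3, a matrix protease, fell from 207 ± 47.8 to 53.8 ± 24.0 (-1.99), Tagln, a smooth muscle protein, from 54.6 ± 19.2 to 12.3 ± 6.11 (-2.11), and Thbs2, a matrix glycoprotein, from 41.0 ± 17.5 to 10.6 ± 7.18 (-1.98). Ccl7, Ccl11, Igfbp7, Nupr1, Ctla2a, Apod and Cyr61 fell by 2.08, 1.92, 2.04, 2.01, 1.99, 1.97 and 1.95 on the log2 scale. Igfbp7 lost its call without wildtype replicate 1 or knockout replicate 3 (adjusted p = 0.0592 and 0.101). Igfbp7 and Nupr1 were lost with a pseudocount of 0.1 (0.0705 and 0.0695), and Thbs2 with only the groups compared (0.0804).

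Higher genes in knockout stem cells were fewer. Rpl29, a ribosomal protein gene, was listed at 37.2 ± 5.52 and 252 ± 49.5 FPKM (2.72), which is uncertain because near-identical copies share its reads. Grik3, a glutamate receptor subunit, rose from 3.11 ± 0.788 to 7.20 ± 0.803 (1.01, SE 0.17, adjusted p = 0.00172), Abca1, a cholesterol transporter, from 12.7 ± 3.11 to 20.6 ± 1.87 (0.68), and Fgd5, a regulator of Cdc42, from 10.3 ± 3.18 to 20.2 ± 3.98 (0.93). Cyp2u1, Zfp185, Tmc8, Depdc7, Shank3, Pik3c2b, Parp16 and Mast3 rose by 1.00, 0.72, 0.69, 0.66, 0.66, 0.60, 0.60 and 0.60 on the log2 scale. Rpl29, Grik3, Cyp2u1 and Zfp185 kept the call with any 1 library left out, but Zfp185 lost it with only the groups compared (adjusted p = 0.0973). Fgd5, Tmc8, Abca1, Depdc7, Shank3, Pik3c2b, Parp16 and Mast3 lost theirs in that fit and with a pseudocount of 0.1. Without wildtype replicate 1, Depdc7 and Parp16 had adjusted p of 0.0758 and 0.0586. Without wildtype replicate 2, Fgd5, Tmc8 and Depdc7 had 0.0509, 0.0634 and 0.148, and without wildtype replicate 3, Fgd5, Tmc8, Abca1, Shank3, Parp16 and Mast3 had 0.0566, 0.0937, 0.0583, 0.101, 0.12 and 0.0952. Without knockout replicate 1, Abca1 and Depdc7 had 0.0522 and 0.0745, and without knockout replicate 2, Tmc8, Depdc7, Shank3, Pik3c2b, Parp16 and Mast3 had 0.0852, 0.12, 0.0899, 0.0533, 0.0901 and 0.0779. Without knockout replicate 3, Fgd5, Tmc8, Abca1, Depdc7, Shank3, Pik3c2b, Parp16 and Mast3 had 0.0813, 0.124, 0.0899, 0.106, 0.156, 0.0604, 0.161 and 0.14.

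Of 12046 genes tested with limma in the cultures, 39 were higher and 704 lower in the knockout, 6 and 284 of them by at least 2-fold. Of the 743 calls, 716 separated the knockout from the wildtype libraries without overlap, which held for 18.3% of all genes tested, where chance gives 10%. The count of higher genes was 76 without wildtype replicate 1, 83 without knockout replicate 1 and 10 without knockout replicate 3. With only the 6 libraries of the cultures in the fit, 4 genes were higher and 251 lower. Quantile normalization gave 88 and 522, so the higher share went from 5.25% to 14.4%, and a pseudocount of 0.1 gave 11 and 388. Of 40 calls of genes named here in the cultures, 19 held under all settings, 17 were lost with a pseudocount of 0.1 and 15 with only the groups compared.

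The fibroblast and feeder cell list fell in knockout cultures by a median of 1.49 over 18 genes, all below 0 (camera adjusted p = 2.82e-16, adjusted p = 0.168 with an estimated correlation); 14 fell, or 15 when adjusted over the list alone. S100a4, a calcium-binding protein of fibroblasts, fell from 102 ± 24.8 to 29.3 ± 5.41 FPKM (-1.75), Postn, a matrix protein, from 49.9 ± 17.4 to 14.9 ± 5.31 (-1.67), and Prrx1 and Pdgfrb, genes of mesenchymal cells, by 1.15 and 1.31 on the log2 scale. The myoid list fell by a median of 1.38 over 8 genes (adjusted p = 2.84e-06, adjusted p = 0.284 with an estimated correlation). Of these 5 fell, or 7 when adjusted over the list alone, Acta2 from 38.8 ± 8.07 to 11.2 ± 6.25 FPKM (-1.85), a call lost with only the groups compared (adjusted p = 0.0541).

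Stress and defence lists fell with them. Whether these falls arose in the germ cells or in feeder or stromal cells of the cultures was not tested. Interferon genes had a median of -0.31 over 14 (adjusted p = 0.00104, adjusted p = 0.284 with an estimated correlation); 4 fell, or 6 when adjusted over the list alone, among them Irf7, an interferon regulator, from 1.34 ± 0.361 to 0.173 ± 0.0662 FPKM (-0.99) and Usp18, a brake on interferon signalling (-0.87). Apoptosis and p53 genes had a median of -0.26 over 17 (adjusted p = 0.000386, adjusted p = 0.284 with an estimated correlation); 5 fell, or 7 when adjusted over the list alone. Cdkn1a, the cell cycle inhibitor p21, fell from 56.5 ± 4.28 to 28.1 ± 4.48 FPKM (-0.99), Phlda3, a p53 target, from 19.6 ± 2.03 to 8.19 ± 0.472 (-1.16), Ccng1, cyclin G, by 0.86 and Fas, a death receptor, by 0.97 on the log2 scale. The interferon call was lost without wildtype replicate 1 (adjusted p = 0.0953). In lists that did not shift, Jun (-0.86), Gadd45b (-0.71), the histone gene Hist1h2bc (-1.40) and Lyz2, a lysozyme of macrophages (-0.69), fell. Lyz2 lost its call without wildtype replicate 1 or 2 or knockout replicate 2 or 3 (0.0956, 0.0955, 0.107 and 0.18). A pseudocount of 0.1 ended the calls of Usp18, Cdkn1a, Phlda3, Fas, Hist1h2bc and Lyz2 (0.101, 0.139, 0.067, 0.0518, 0.0682 and 0.40), and a fit of only the groups compared those of Usp18, Fas, Gadd45b and Lyz2 (0.118, 0.0726, 0.0605 and 0.13).

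The 5 lists that shifted up in knockout cultures did so by smaller amounts, with 0 members called in any of them, also when adjusted over the list alone. They were not all lists of germ cell genes, and other germ cell lists did not shift. Whether a changed share of germ cells in the cultures shifted the 5 lists was not tested. Genes of undifferentiated spermatogonia and self-renewal had a median of 0.29 over 26 (adjusted p = 0.00462, adjusted p = 0.39 with an estimated correlation). Utf1, Lhx1 and Bcl6b, regulators of stem cells, stood at 6.28 ± 2.34 and 12.5 ± 4.45, 25.7 ± 7.84 and 36.4 ± 4.03, and 24.9 ± 6.45 and 39.9 ± 14.0 FPKM. Nanos2, an RNA-binding protein of stem cells, had a log2 fold change of -0.43. The piRNA pathway had a median of 0.20 over 22, double-strand breaks and recombination 0.13 over 32, cohesin and separase 0.10 over 19, and G2/M genes 0.066 over 27 (adjusted p = 0.00233, 0.0143, 0.024 and 0.033, with an estimated correlation adjusted p = 0.613, 0.613, 0.537 and 0.617). Differentiating spermatogonia genes had a median of -0.024 over 12, where Crabp1, a retinoic acid binding protein, fell from 145 ± 43.2 to 55.4 ± 9.98 FPKM (-1.34). The piRNA call was lost without wildtype replicate 2 (adjusted p = 0.0864), the cohesin call without that library or knockout replicate 1 (0.0639 and 0.0786), and the G2/M call without wildtype replicate 1 or knockout replicate 2 (0.479 and 0.211), with a median of -0.0052 in the first of these. Quantile normalization ended the cohesin and G2/M calls (adjusted p = 0.0713 and 0.0935). Crabp1 was lost without knockout replicate 3 (0.0609) or with a pseudocount of 0.1 (0.10). Utf1 passed without wildtype or knockout replicate 1 (0.0471 and 0.0207), Bcl6b without knockout replicate 1 (0.0228), and Lhx1 and Nanos2 without wildtype replicate 2 (0.0171 and 0.0253).

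The other lists did not shift in knockout cultures, with camera adjusted p from 0.0689 to 0.865. Their medians were 0.087 for germ cell RNA-binding proteins, 0.029 for G1/S, 0.019 for microRNA machinery, 0.0027 for the synaptonemal complex, 0.0011 for pachytene genes and 0.00050 for Y-linked genes. They were -0.033 for Sertoli cells, -0.072 for X-linked genes, -0.098 for spermatids, -0.0998 for meiotic entry, -0.12 for immediate early and heat shock genes, -0.15 for macrophages, -0.17 for ribosomal proteins and -0.19 for histones. Of the X-linked genes 1 rose and 34 fell, or 1 and 39 when adjusted over the list alone. The numbers that fell were 1 in meiotic entry, 1 in macrophages, 2 in the heat shock list and 4 in histones, or 2, 3, 4 and 4 when adjusted over the list alone. The camera direction was up for differentiating (mean -0.092), synaptonemal (mean -0.027) and Y-linked genes (mean -0.0013). The ribosomal list passed without wildtype replicate 1, 2 or 3 or knockout replicate 3 (-0.32, -0.33, 0.096 and -0.28), upward in the third of these. The X-linked list passed without wildtype replicate 1 or knockout replicate 1 or 2 (-0.12, -0.082 and -0.073), the G1/S list without wildtype replicate 3 (0.13), and the histone list without knockout replicate 2 (-0.26). Without knockout replicate 3 the microRNA machinery, macrophage and heat shock lists passed (0.15, -0.54 and -0.12). The histone list passed with no filter (-0.17, adjusted p = 0.0439). Endothelial, erythroid and Leydig genes were too few to test.

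**Figure D1:**
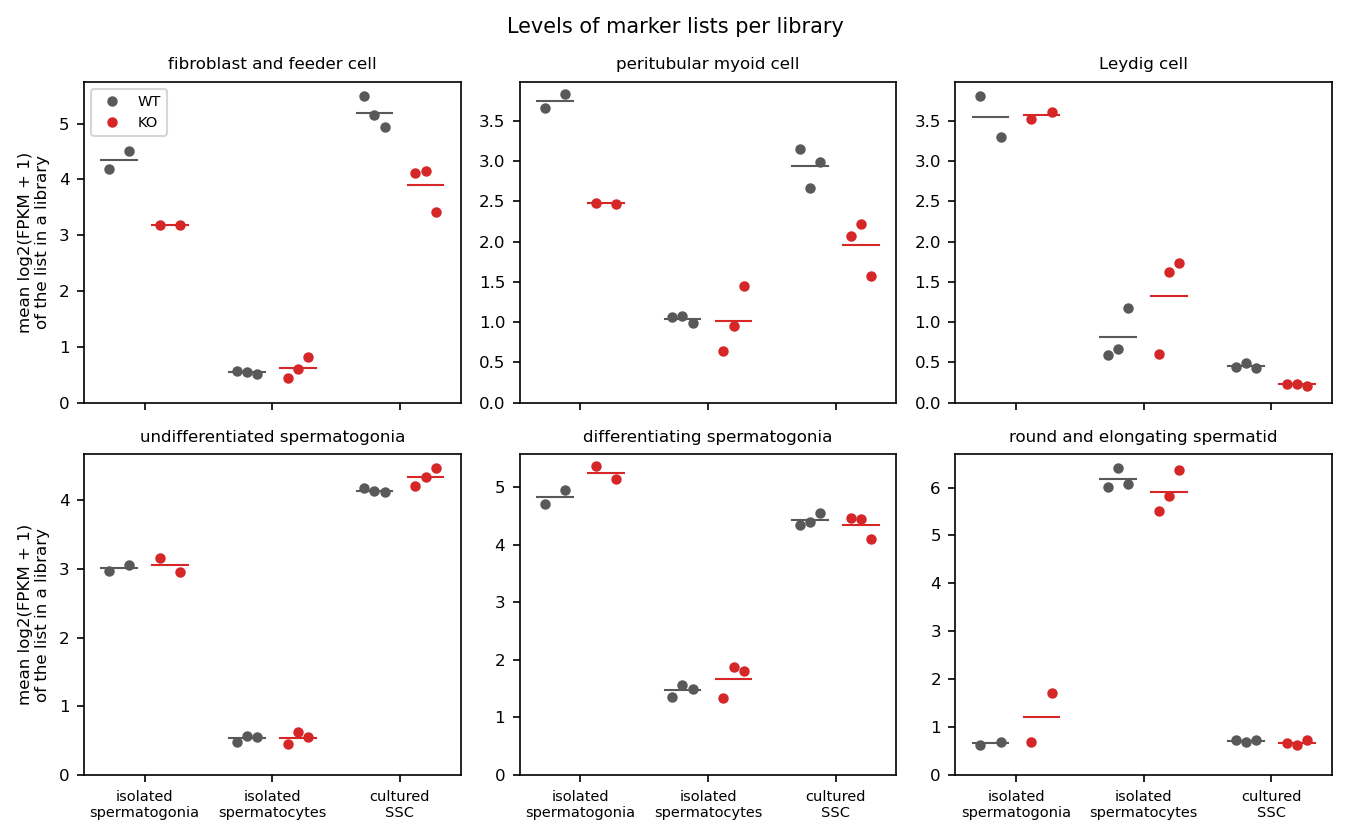
Mean log2(FPKM + 1) of the genes of 6 marker lists in each library (points; bars are group means), for wildtype (grey) and knockout (red) in the 3 cell types. The fibroblast and feeder cell list lay at 4.19 and 4.50 in wildtype and at 3.19 in both knockout spermatogonia libraries, and at 4.93 to 5.50 in wildtype against 3.42 to 4.14 in knockout cultures.

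**Figure D2:**
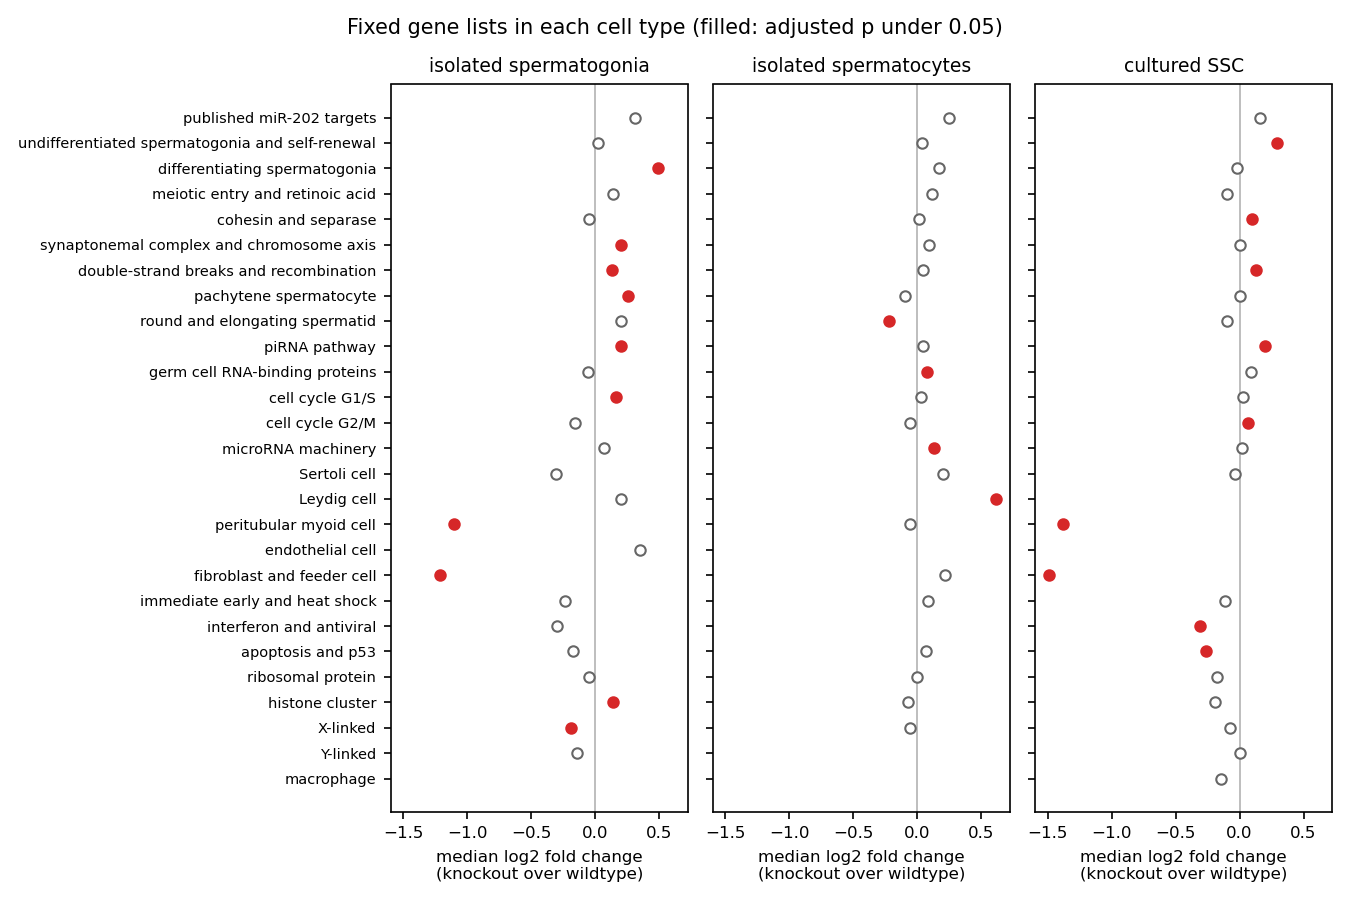
Median log2 fold change, knockout over wildtype, of each fixed gene list (vertical axis) in the 3 cell types (panels); filled points had a camera adjusted p under 0.05 with the preset correlation. The lowest medians were those of the fibroblast and feeder cell list, -1.21 in isolated spermatogonia and -1.49 in the cultures.

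With an estimated correlation between genes, 0 of the 26, 23 and 25 lists tested in isolated spermatogonia, spermatocytes and cultured stem cells passed, where the preset correlation called 10, 4 and 9. The smallest adjusted p were then 0.236, 0.537 and 0.168. With the preset correlation 6 lists passed in spermatogonia without wildtype replicate 1, and in spermatocytes 2 without wildtype replicate 1 and 8 without knockout replicate 1.

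Genes reported as targets of miR-202 were measured in every group, and none was called with the model of all libraries. Whether they were chosen on these samples is not given in the sources used here, so their list is not independent evidence of a direction. Dmrtb1, a regulator of the exit from mitosis, stood at 16.1 ± 2.57 and 26.7 ± 0.245 FPKM in wildtype and knockout spermatogonia (0.71, adjusted p = 0.187; adjusted p = 0.00857 with only the groups compared, which called it), at 468 ± 47.2 and 439 ± 65.0 in spermatocytes, and at 2.91 ± 1.42 and 4.29 ± 1.44 in cultures. Stra8, required for the start of meiosis, stood at 39.4 ± 8.95 and 49.8 ± 15.7 FPKM in spermatogonia (0.31, adjusted p = 0.827), at 1.14 ± 0.643 and 1.64 ± 1.04 in spermatocytes (0.25), and at 2.76 ± 2.19 and 1.59 ± 1.25 in cultures (-0.53, adjusted p = 0.601). Espl1, the separase that cleaves cohesin, had log2 fold changes of 0.10, 0.063 and 0.38 in spermatogonia, spermatocytes and cultures, Cpeb1, a translational regulator, 0.35, 0.46 and 0.16, and Rbfox2, a splicing factor, -0.19, 0.30 and -0.062. The list of 5 genes had medians of 0.31, 0.25 and 0.16 (camera adjusted p = 0.214, 0.176 and 0.312), with 0 members passing when adjusted over the list alone. Stra8 had a log2 fold change of -0.0095 in spermatogonia without knockout replicate 1, and Espl1 one of -0.11 in spermatocytes without wildtype replicate 3.

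Genes that rise in spermatocytes were followed in the knockout, to ask whether the meiotic programme moved. For each test they were chosen by the means of wildtype groups outside that test, within the fit of all 16 libraries. The p-values were adjusted over the rising and falling genes in spermatogonia and cultures only, fewer tests than for the fixed lists. Of the 200 genes with the largest rise in wildtype spermatocytes over wildtype cultures, 65 could be tested in isolated spermatogonia and lay higher in the knockout, with a median of 0.36 (camera adjusted p = 8.94e-12, adjusted p = 0.0479 with an estimated correlation). The median was 0.25 without knockout replicate 2 and 0.53 without wildtype replicate 2, and the call held in each of the 4 such fits. A gene could meet the minimum FPKM through the 2 knockout libraries alone, so which genes made up the 65 depended in part on the values tested. With the minimum met in both wildtype libraries, an alternative chosen after seeing the data, 39 genes had a median of 0.27 (adjusted p = 1.52e-07, adjusted p = 0.0413 with an estimated correlation). The 200 genes with the largest fall had a median of -0.13 over 188 tested (adjusted p = 0.247) and passed without wildtype replicate 1 (-0.10, adjusted p = 0.0421). In cultured stem cells, genes that rise in spermatocytes relative to isolated spermatogonia had a median of -0.019 over 49 tested (adjusted p = 0.512), and genes that fall -0.27 over 183 (adjusted p = 1.73e-08, adjusted p = 0.435 with an estimated correlation). Stromal and feeder genes are among the kinds that fall in this way: the mean level of the fibroblast and feeder cell list was 4.19 and 4.50 in wildtype spermatogonia and 0.512 to 0.562 in wildtype spermatocytes, and that list fell by a median of 1.49 in knockout cultures.

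The knockout effects of the cell types were compared with each other. Genes lower in knockout spermatogonia and in knockout cultures overlapped: of 11141 genes tested in both, 457 and 528 were called lower and 174 were shared, where independent lists would share 21.7 (Fisher's exact test, p = 3.48e-118). The 2 comparisons set different libraries against each other, but both came from a single fit that shares each gene's spread. Fisher's test also takes genes as independent, which they are not, so its p overstates the evidence. Of the higher genes, 76 and 26, 2 were shared where 0.177 would be (Fisher's exact test, p = 0.0134). Across these genes, which are not independent replicates, the log2 fold changes correlated with r = 0.35 and rho = 0.243. Isolated spermatogonia and spermatocytes had r = 0.00665 and rho = 0.0117, and spermatocytes and cultures r = 0.0445 and rho = 0.135. By the test of the difference itself, 234 genes differed between spermatogonia and cultures, 295 between spermatogonia and spermatocytes, and 280 between spermatocytes and cultures. A pseudocount of 0.1 left 8, 17 and 11 such genes. With 1 library left out the first count was 89, 76, 91 and 71 without wildtype replicates 1 and 2 and knockout replicates 1 and 2 of the spermatogonia. The second count was then 145, 102, 179 and 109, and it was 162, 166 and 189 without wildtype spermatocyte replicates 1, 2 and 3 and 195 without knockout replicate 3. The count for spermatocytes and cultures was 96, 130 and 137 without wildtype spermatocyte replicates 1, 2 and 3, 181 and 133 without knockout replicates 2 and 3, and 155 and 147 without wildtype replicate 1 and knockout replicate 3 of the cultures.

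Transcripts with a site for miR-202 were tested for a shift in the knockout, since a lost microRNA would leave its targets higher. In isolated spermatogonia, 731 of 11594 genes had a match to the miR-202-3p seed (ATACCTC) in the 3' UTR and 980 a match to the miR-202-5p seed (CATAGGA). Their shifts were 0.0034 and 0.021 on the log2 scale, in spermatocytes -0.013 and -0.0016, and in cultures 0.0016 and 0.0046. Ranked by the absolute t statistic of the shift among the words of 7 bases, none passed, with adjusted p from 0.648 to 0.926 over the 6 tests. Without wildtype spermatogonia replicate 2 the miR-202-5p shift in spermatogonia was 0.035, past 0.05 before adjustment. A simulated shift of 0.1 was found in each cell type, with estimates of 0.129, 0.103 and 0.0947.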

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

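The tests of all somatic cells, of both scalings, of a uniform dilution, of a minimum FPKM in wildtype libraries and of genes tested in both cell types were chosen only after the results were seen. The results listed first were singled out because the knockout effect differed between cell types by a test of the difference itself. Values are the log2 fold change in the cell type named first minus that in the other. With a pseudocount of 0.1 the test called 8, 17 and 11 genes in the comparisons of the next 3 paragraphs, against 234, 295 and 280 with a pseudocount of 1. A gene near 0 in a cell type cannot fall there on this scale, so a difference can come from absence in 1 cell type: of the differing named genes, 15 of 30, 4 of 21 and 5 of 27 were tested in both cell types.

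Between isolated spermatogonia and cultured stem cells, 30 named genes and 3 lists differed. The lists were differentiating spermatogonia (0.54), histones (0.62) and G2/M (-0.23); with an estimated correlation none of the 3 passed (adjusted p = 0.878, 0.636 and 0.878). Over genes tested in both cell types the 3 passed with the preset correlation (0.54, 0.30 and -0.23). None of them did with an estimated one (camera adjusted p = 0.625 for each). Genes with a higher value in spermatogonia were Mcpt4 (2.61), Tbx1 (1.43), Trnp1 (1.84), Crip2 (1.68), Hcn2 (0.91), Gadd45g (1.39), Ovol1 (0.88), Ctla2a (2.97), Ccl8 (2.47), Ccl7 (1.76), Ccl11 (1.83), Ccl2 (1.56), Mmp3 (1.92), Apod (1.95), Cyr61 (1.92), S100a4 (1.48), Gadd45b (0.86) and Phlda3 (1.44). Genes with a lower value were Pdlim3 (-2.43), Casq2 (-2.36), Col4a4 (-2.31), Lama2 (-2.07), Fgl2 (-1.98), Myh11 (-1.78) and Pdgfra (-1.12). The heat shock genes Hspa1a (-1.60) and Hspa1b (-1.71) were lower too, as were Rpl29 (-3.65), Cyp2u1 (-1.18) and Zfp185 (-1.04).

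Between isolated spermatogonia and spermatocytes, 21 named genes and 8 lists differed. The lists were spermatids (0.67), pachytene spermatocytes (0.35), piRNA pathway (0.17), histones (0.11), X-linked genes (-0.19), heat shock (-0.32), myoid cells (-1.20) and fibroblasts (-1.24). None of the 8 passed with an estimated correlation (adjusted p from 0.0784 to 0.796). On the spermatogonia side the spermatid difference rested on 1 library. The mean level of that list was 1.72 in knockout replicate 2 and 0.628 to 0.696 in the other spermatogonia libraries. Without knockout replicate 2 its median in spermatogonia was -0.078. Only 7 spermatid genes, 5 fibroblast genes and 5 myoid genes were tested in both cell types. Over such genes spermatids (0.71), pachytene (0.33), piRNA (0.17), histones (0.37), myoid cells (-1.39) and fibroblasts (-1.10) passed with the preset correlation. So did the synaptonemal list (0.20, adjusted p = 0.0434), and X-linked and heat shock genes did not (adjusted p = 0.885 and 0.124). None of the lists that passed there did so with an estimated correlation (camera adjusted p from 0.147 to 0.668). Higher in spermatogonia were Mcpt4 (2.61), BC048609 (1.60), Tbx1 (1.31), Hcn2 (1.03) and Ovol1 (0.94). Lower were Acta2 (-2.91), Pdlim3 (-2.69), Casq2 (-2.36), Col4a4 (-2.36), Mfap4 (-2.29), C1qtnf3 (-2.25), Bgn (-2.19), Cdh11 (-2.14), Fgl2 (-2.08), Myh11 (-2.08), Lama2 (-2.05), Col6a1 (-1.82), Pdgfra (-1.73), Hspa1a (-1.67), Hspa1b (-1.57) and Tpm2 (-1.49).

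Between spermatocytes and cultured stem cells, 27 named genes and 9 lists differed. The lists were fibroblasts (1.52), myoid cells (1.19), Leydig cells (0.93), interferon (0.37), apoptosis and p53 (0.22), piRNA pathway (-0.049), G2/M (-0.14), undifferentiated spermatogonia (-0.20) and spermatids (-0.22). With an estimated correlation none of the 9 passed (adjusted p from 0.143 to 0.604). Over genes tested in both cell types fibroblasts (1.87, 5 genes), myoid cells (1.31, 5 genes) and G2/M (-0.14) passed with the preset correlation, and fibroblasts alone with an estimated one (adjusted p = 0.0444). The p53, undifferentiated and spermatid lists did not (adjusted p = 0.153, 0.0579 and 0.265), nor did piRNA, just above the threshold, and interferon and Leydig genes were too few. Higher in spermatocytes were Igfbp7 (2.83), Ccl8 (2.64), Tagln (2.22), Nupr1 (2.07), Ccl7 (2.03), Ctla2a (2.00), Mmp3 (1.96), Apod (1.96), Cyr61 (1.88), Ccl11 (1.86), Ccl2 (1.76), S100a4 (1.75), Postn (1.58), Hist1h2bc (1.52), Pdgfrb (1.29), Cdkn1a (1.21), Prrx1 (1.20), Ssr4 (1.13), Gadd45b (1.09), Phlda3 (1.08), Fas (1.01), Irf7 (1.00) and Ccng1 (0.93). Lower were BC048609 (-1.09), Grik3 (-0.999), Zfp185 (-0.96) and Cib4 (-0.69). Of 100 splits of these libraries, 7 gave as many differing genes as the 280 of the real one, with 704 the highest of the others. All 7 kept the real culture groups or their mirror image, and other culture groups gave at most 105 genes. Chance was thus not excluded for the spermatocyte side alone. The split with 704 joined the real culture groups to the set of spermatocyte libraries that parts wildtype replicate 3 and knockout replicates 2 and 3 from the rest.

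Myoid and fibroblast genes were lower in knockout spermatogonia. A share lowered alike for all somatic cells is argued against. The 34 Sertoli, Leydig and endothelial genes had a median of -0.115, against -1.19 for the 27 stromal genes. The permutation test gave p = 1e-05, the smallest that 100000 resamples can give, but it takes genes as independent. The stromal genes were also singled out for their fall. By list the medians were 0.204 for Leydig, 0.35 for endothelial and -0.304 for Sertoli genes (14 of 18 below 0). A smaller fall in the share of Sertoli cells is thus not argued against. Scaling of the FPKM values is argued against, since the median nearest to 0 under the 2 scalings was -1.06. A lower share of myoid and stromal cells in the knockout isolates stays open: of a second list of 28 stromal genes written before the test, 96.4% lay below 0, with a median of -1.22. Of that list 13 genes were called lower and 0 higher by limma. The most abundant were Lgals1, Col4a1, Serpinh1, Lamb1, Pcolce and Fstl1. They stood at 132 and 73.8, 91.1 and 34.3, 80.3 and 30.2, 72.6 and 28.7, 69.6 and 43.4, and 58 and 14.3 FPKM in wildtype and knockout. Lgals1, Col4a1 and Pcolce were not called. The isolates may thus have differed in their stromal share, and lower expression within those cells in the knockout was not tested.

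Spermatocyte genes were higher in knockout spermatogonia. A smaller stromal share that raises all germ cell genes alike stays open. The 23 undifferentiated genes had a median of 0.0243, against 0.36 for the 65 spermatocyte genes (permutation test, p = 0.003), but the knockout values helped to choose the 65. With the minimum FPKM met in both wildtype libraries, 39 genes had 0.27 (permutation test, p = 0.0525). RNA or cells of adult spermatocytes in the knockout isolates stay open as well. The difference between knockout and wildtype means of abundant spermatocyte transcripts had a median of 0.0936% of their spermatocyte level (quartiles 0.0555% and 0.13%), and that of the spermatocyte genes 0.135% (quartiles 0.0585% and 0.307%). Of the 39 abundant transcripts, 11 were higher in both knockout than in both wildtype libraries, and they were chosen for low wildtype values, which favours some rise. The values came apart by library: in knockout replicate 2 they were 0.16% and 0.19%, and in knockout replicate 1 0.00553% and 0.0872%. Such RNA may account for part of the pattern in replicate 2, and earlier meiotic expression in the knockout, which the study's design allows, remains an untested candidate explanation in replicate 1. The call for these genes held without knockout replicate 2 (0.25).

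Fibroblast and feeder genes were lower in knockout cultures. Scaling of the FPKM values is argued against, with a median nearest to 0 of -1.47. A lower share of feeder or stromal cells in the knockout cultures stays open: 89.7% of a second list of 29 genes lay below 0, with a median of -1.23. Lgals1, Fbln2 and Timp2 stood at 350 and 198, 105 and 33.7, and 57.3 and 17 FPKM, while Nid1 and Nid2 stood at 77.8 and 98.9 and 62.5 and 79.8. The cultures may have differed in their share of such cells; lower expression of these genes within the same cells was not tested. The labels do not say whether feeder cells were removed.

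In spermatocytes and in cultures the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Since a split has no knockout side, the larger of its 2 directions was set against the real count. In spermatocytes, all 10 splits gave as many higher genes as the real 0, as they must, so that count says nothing (highest other 395). For the 1 lower gene it was 7 splits, with the same 395, a count of higher genes. There 7 splits gave as many shifted lists as 4 (10), 2 a miR-202-3p shift as large as 0.0127 (0.019) and 6 a miR-202-5p shift as large as 0.00161 (0.0051). The split that gave 395 called far more genes than the real one, which points to a structure of the samples other than the genotype. In cultures, 1 split, the real one, gave as many higher genes as 39 (highest other 12), 1 as many lower genes as 704 (12), 1 as many lists as 9 (7) and 1 an absolute median of the rising or falling list as large as 0.266 (0.147), a value of the genes that fall in spermatocytes. For the miR-202-3p shift of 0.00156 it was 10 splits (0.0187), and for the miR-202-5p shift of 0.00459 it was 3 (0.00716).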

How the results depend on the processing

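The term for a set of spermatocyte libraries, the block with crossed numbers and the minimum FPKM in wildtype libraries were chosen after seeing the data. With an estimated correlation, 0 of the fixed lists passed in each cell type. The genes that rise in spermatocytes passed in knockout spermatogonia (camera adjusted p = 0.0479), but their p was adjusted over fewer tests than the fixed lists. The 2 outcomes are thus not on the same footing. Among the fixed lists that did not pass, pachytene genes in spermatogonia had an unadjusted camera p of 0.0106 with an estimated correlation. Fibroblast and feeder genes in cultures had 0.00673. With a pseudocount of 0.1, 26 genes were higher and 165 lower in spermatogonia, 0 lower in spermatocytes (limma), and 11 higher and 388 lower in cultures, and 8 (spermatogonia and cultures), 17 (spermatogonia and spermatocytes) and 11 (spermatocytes and cultures) differed between cell types. This setting spreads genes with low values. Without a filter, which tests more genes, 182 were higher in spermatogonia, 6 lower in spermatocytes and 66 higher in cultures. Medians in spermatocytes were then 0.0113 for myoid, 0.0193 for histone and 0.0166 for X-linked genes, and in cultures -0.00768 for the synaptonemal complex.

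With median-ratio scaling, 3 genes were lower in spermatocytes and the ribosomal median there was -0.0039. With quantile normalization, 430 genes were higher in spermatogonia, 5 lower in spermatocytes, 88 higher in cultures, and 147 differed between spermatocytes and cultures. Medians were then 0.00888 for cohesin and 0.0717 for RNA-binding proteins in spermatogonia, and 0.082 for differentiating, 0.00263 for meiotic entry, 0.0829 for Sertoli and 0.000124 for X-linked genes in cultures, and Dmrtb1 had 0.0128 in spermatocytes. With a replicate block, 69 genes were higher in spermatogonia, 0 lower in spermatocytes and 18 higher in cultures, and 74 and 149 differed between spermatogonia and cultures and between spermatogonia and spermatocytes. With only the groups compared, which have fewer samples, the counts were 251 higher in spermatogonia, 0 lower in spermatocytes, 4 higher and 251 lower in cultures, and 41, 574 and 166 between cell types. With the set term, 12 genes were lower in spermatocytes, and medians were -0.0533 for undifferentiated, -0.00252 for cohesin, -0.0556 for synaptonemal, -0.0414 for recombination, -0.019 for piRNA, -0.0417 for G1/S, -0.0275 for heat shock and -0.0813 for ribosomal genes.

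The seed shifts without covariates were -0.0549 (3p) and -0.0434 (5p) in spermatogonia and 0.0124 and 0.0278 in spermatocytes. With the shortest UTR they were -0.00373 (3p, spermatogonia), 0.00301 (5p, spermatocytes) and -0.00569 (5p, cultures). With a pseudocount of 0.1 the 3p shift in spermatogonia was -0.000689, and with an 8-base match it was -0.0032, and the 5p shift in cultures -0.00691. None of these passed.

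With each library left out in turn, spermatogonia gave 22 to 54 higher and 216 to 348 lower genes, spermatocytes 0 to 8 and 0 to 36, and cultures 10 to 83 higher. Lists that passed numbered 6 to 12 in spermatogonia and 2 to 8 in spermatocytes. Genes that differed numbered 71 to 278 between spermatogonia and cultures, 102 to 343 between spermatogonia and spermatocytes and 96 to 409 between spermatocytes and cultures, and 2595 to 3950 genes were higher in wildtype cultures than spermatogonia. A lone library was assumed to vary like the other groups.

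Medians in spermatogonia then ranged from -0.0168 to 0.238 for G1/S, -0.0958 to 0.0453 for cohesin, -0.108 to 0.0656 for RNA-binding proteins, -0.00521 to 0.381 for histones, -0.241 to 0.458 for Leydig, -0.00699 to 0.152 for meiotic entry, -0.0812 to 0.137 for microRNA machinery, -0.187 to 0.0692 for ribosomal, -0.0783 to 0.296 for spermatid and -0.145 to 0.187 for undifferentiated genes. Stra8 ranged from -0.00952 to 0.63 and the 5p shift from 0.0132 to 0.035.

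In spermatocytes they ranged from -0.0231 to 0.0787 for G1/S, -0.0353 to 0.0787 for cohesin, -0.0525 to 0.0812 for recombination, -0.142 to 0.00517 for histones, -0.0788 to 0.271 for heat shock, -0.387 to 0.353 for myoid, -0.0601 to 0.095 for ribosomal, -0.615 to 0.543 for Sertoli, -0.0407 to 0.17 for synaptonemal, -0.0602 to 0.0538 for undifferentiated and -0.18 to 0.154 for X-linked genes. Espl1 ranged from -0.113 to 0.152 and the 5p shift from -0.00489 to 0.00072.

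In cultures they ranged from -0.0326 to 0.13 for G1/S, -0.00517 to 0.153 for G2/M, -0.111 to 0.102 for differentiating, -0.0834 to 0.0633 for the genes that rise in spermatocytes, -0.0322 to 0.15 for microRNA machinery, -0.0154 to 0.0782 for pachytene, -0.327 to 0.0958 for ribosomal, -0.306 to 0.0291 for spermatid, -0.175 to 0.0369 for Sertoli, -0.148 to 0.114 for synaptonemal and -0.0855 to 0.0483 for Y-linked genes, and the 3p shift from -0.00931 to 0.0069.

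Counting values given above as well, 112 refits of called lists kept call and direction and 33 lost the call, and with a library left out 99 kept it, 20 lost it and 3 changed sign. For called genes named here, 480 kept it and 81 lost it, and with a library left out 297 and 97. The replicate numbers were not taken to pair samples. To check them, each gene's group mean was subtracted, and the remainders were correlated between wildtype and knockout libraries of the same number. Without that step the lowest correlation between libraries was 0.985 in spermatogonia, 0.990 in spermatocytes and 0.979 in cultures. The remainders correlated at -0.17 in spermatogonia, where both numbers must give the same value. They correlated at 0.26, -0.34 and -0.17 in spermatocytes, and at -0.00017, -0.063 and 0.23 in cultures. By these remainders, 1 of 3 wildtype libraries correlated best with its own number in spermatocytes and in cultures. Of named calls, 8 of 39 in spermatogonia, the 1 in spermatocytes and 6 of 40 in cultures missed the threshold with the replicate block. Mki67 in spermatogonia (-0.774, adjusted p = 0.0457) and the ribosomal list in cultures (-0.173, adjusted p = 0.0243) passed. With crossed numbers 610 genes were lower in spermatogonia. Apart from fewer samples or more genes tested, the cause was not tested. Depth was unknown.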

Other observations

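The set of spermatocyte libraries was examined after the splits were seen, as was the let-7 word; the mast cell test was written before its result was seen. Wildtype replicate 3 and knockout replicates 2 and 3 differed from the other 3 spermatocyte libraries in 414 genes. Insl3 stood at 45, 81.8 and 98 FPKM against 8.79, 12.4 and 10.9, Agt, angiotensinogen, at 3.52, 5.35 and 7.25 against 0.657, 0.489 and 1.14, and Ptgds, a prostaglandin enzyme, at 6.16, 10 and 13 against 2.81, 2.66 and 1.97. The Leydig list had a median of 1.16 between these sets. With the set as a term, 12 genes were lower in knockout spermatocytes at an adjusted p under 0.05, with Tmem95 (-0.97), BC048609 (-1.21), Fam83e (-0.75), Nipsnap3a (-0.82) and Cib4 (-0.72) among them, and 0 were higher by limma, where 590 genes had an unadjusted p under 0.05 in either direction.

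Mast cell proteases were seen in the knockout spermatogonia and near 0 in the wildtype. Tpsb2 stood at 3.18 and 4.20 FPKM in knockout libraries, Cma1 at 3.35 and 4.52, and Cpa3 at 1.45 and 1.72, each at most 0.505 in wildtype libraries. Mast cells in the knockout isolates may be their source. Of 12 other mast cell genes, 5 were higher in both knockout than in both wildtype libraries, where chance gives 16.7% for each gene. Hdc and Gata2 were not, Fcer1a was listed at 0, and most of the 12 lay below 1 FPKM, so the test left this open.

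The seed of let-7, an abundant microRNA family, is close to that of miR-202-3p. The estimates for the let-7 word were 0.037 in spermatogonia, -0.021 in spermatocytes and 0.022 in cultures. Words at least as extreme, without adjustment, numbered 251 of 16364, 98 of 16332 and 1691 of 16368, so the culture estimate did not stand out.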
